A study of Mus musculus with 58 samples.

How the data were processed

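Messenger RNA of prefrontal cortex was sequenced in 58 libraries made with a stranded poly(A) protocol. The deposited table holds 1 value per gene and library for 18088 Ensembl genes, of which 2 were 0 in every library. Per the submitters' processing notes the authors quantified transcripts with Salmon 0.11.2 on GRCm38 and used DESeq2 1.19.11 in R 3.6.0. The values are a signal on a normalised scale, which the authors obtained by dividing read counts per gene by a size factor per library. Each library's values were checked to be whole reads divided by 1 factor, and 100% of them were within 0.001 read of a whole number once multiplied back. In 4 libraries the factor lay so close to 1 that the spacing of the values alone did not settle it. The recovered totals were 24.0 to 36.7 M reads per library. How transcripts were summed to genes and the strand setting of the counting are not given in the sources used here. Columns were matched to groups by the library names in the labels, and no column was left unmatched.

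Gene symbols, positions, transcript GC content and length came from the reference annotation. GC content and length were available for 16623 of the 16632 genes tested (99.95%). There were 11 gene IDs without a symbol and 40 that shared one.

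The test was limma 3.58.1 in R 4.3.3 with a trended and robust empirical Bayes fit on log2(value + 1), over the genes with a mean value of at least 10 (16632). A single fit held 12 group means, and 24 contrasts were taken from it, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. The contrasts were genotype under vehicle, each drug in each genotype, the same within each sex, the difference between the sexes, the interaction of drug and genotype, and drug-treated HT against vehicle WT. Contrasts over both sexes are the mean of the female and male effects. The Arid1b level per library, and 39 gene lists for cell types, synapses, chromatin, metabolism and drug pathways, were set beforehand. Lists were tested with camera at a preset correlation of 0.01 in the 5 main comparisons, adjusted over 195 tests together, and again with an estimated correlation. Members were also adjusted over the list alone. The comparisons, tests, gene lists and first alternatives were chosen before the data were examined.

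The rule for named genes was fixed too. In each main comparison and direction it took up to 10 genes with the smallest p among those with an adjusted p under 0.05 and the same sign in both sexes. Arid1b was always named. In each described list it took up to 4 members with the smallest p. In the comparisons within a sex, the interactions and the treated HT comparisons it took up to 4 genes per direction, or 2 per direction that did not pass where none did. Genes without a symbol were skipped.

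Contrasts were tested on simulated data (real group sizes, 16632 genes, 200 changed). At 1.25-fold, 1.5-fold and 2-fold the genotype contrast recovered 49.3%, 83.6% and 93.9% of the changed genes, with 10 unchanged genes called. Fluoxetine in WT recovered 44.8%, 82.1% and 93.9%, with 3, and lithium in HT males, with 5 libraries per group, 35.8%, 67.2% and 86.4%, with 5. With edgeR the genotype contrast recovered 49.3%, 77.6% and 89.4%, with 12. When a GC trend was added to WT lithium females, 3540 unchanged genes were called, and 8 after the correction described next, with 143 and 133 changed genes recovered. The other simulations held no such trend, so their false calls do not measure those in real libraries.

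The alternatives set beforehand were quantile normalisation, no filter on low values, a pseudocount of 5, library weights, a block for libraries with the same replicate number, a fit of only the groups compared, each library left out in turn, the estimated correlation, and a split of shared vehicle groups. A DESeq2 test was set beforehand only for a table of counts and was not run. Alternatives chosen after seeing the data were the edgeR 4.0.16 quasi-likelihood test on the recovered reads (17991 genes), and a correction of each library for a spline (5 degrees of freedom) of GC content and length, fitted on 13267 genes with a mean log2 above 6. The others chosen then were the GC slope of each library as a covariate, the olfactory marker score as a covariate, and leaving out HT fluoxetine male 1, HT lithium female 4 and HT lithium male 5 together. These 3 were picked by eye for a low GC slope, a lack of Xist and reads of choroid plexus (Ttr at 9013), and other libraries with outlying values were kept. The GC slope is the change of log2 expression, relative to the mean of all libraries, per 10 percentage points of transcript GC content. GC content was computed with Biostrings 2.70.1 from the reference transcripts. By edgeR 6 genes were called for genotype, 6055 and 3818 for fluoxetine and lithium in HT, and 6413 and 1778 in WT. A comparison of fluoxetine with lithium within each sex, and a score of each library along the mean fluoxetine effect in the other libraries, were added as well.

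Relations between contrasts were set beside 100 simulations of unchanged groups that share the same libraries and 20 splits of the shared vehicle group. Scores of groups of libraries were compared with 2-sided permutation tests (100000 resamples), adjusted over 3 tests. Over all genes, residuals of libraries with the same replicate number correlated little more than others (mean 0.0235 against -0.00576 over 309 pairs). Such libraries were therefore not treated as pairs. The number did track the olfactory markers: replicate 1 scored 1.295 to 2.068 in most groups, but -1.127 and -1.374 in HT and WT lithium females. No 2 libraries of a group were duplicates (lowest chi-square per degree of freedom 5.45 over 112 pairs). No library was left out of the reported values. Isoforms were not examined, since the table holds genes.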

Results

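RNA sequencing measured messenger RNA in the prefrontal cortex of C57BL/6N mice carrying 1 disrupted copy of Arid1b (labelled HT, heterozygous) and of wild-type mice (WT). Arid1b encodes a DNA-binding subunit of the BAF chromatin remodelling complex. The mice received vehicle, the serotonin reuptake inhibitor fluoxetine or the mood stabilizer lithium through maternal milk from postnatal day 3 to day 24, and tissue was taken on day 25. The 58 libraries formed 12 groups of genotype, treatment and sex, with 5 libraries in each group except the vehicle HT females and the vehicle WT males, which had 4 each. Libraries held between 23977609 and 36689430 reads (mean 30.75 M). Mean depth was 27.7 M reads in the 18 vehicle libraries, 33.2 M in the 20 fluoxetine libraries and 31.0 M in the 20 lithium libraries. The labels did not state that each library came from a separate animal, so the p-values measured the spread between these libraries. No litter, batch or sequencing date was recorded. The drugs were given through milk and so to whole litters, and libraries of 1 litter would not be independent in the drug comparisons. The number of litters per group is not known.

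Arid1b (ENSMUSG00000069729, GRCm38 chromosome 17, 4994332 to 5347656) was lower in HT than in WT libraries. Its mean normalised read count was 2018 ± 61.3 (SD, n = 9) in vehicle HT libraries and 2556 ± 80.8 (SD, n = 9) in vehicle WT libraries. Vehicle HT libraries lay between 1962 and 2143, and vehicle WT libraries between 2450 and 2700, with no overlap. The counts were 2366 ± 159 (SD, n = 10) in HT libraries with fluoxetine, 2219 ± 162 (SD, n = 10) in HT libraries with lithium, 2938 ± 141 (SD, n = 10) in WT libraries with fluoxetine and 2720 ± 251 (SD, n = 10) in WT libraries with lithium. The Y-linked gene Ddx3y averaged 1290 in the 29 libraries labelled male and 0.263 in the 29 labelled female. Xist, which is transcribed from the inactive X chromosome, averaged 20.5 in males and at least 16800 in every female library but HT lithium female replicate 4, which had 3.74.

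**Figure D1:**
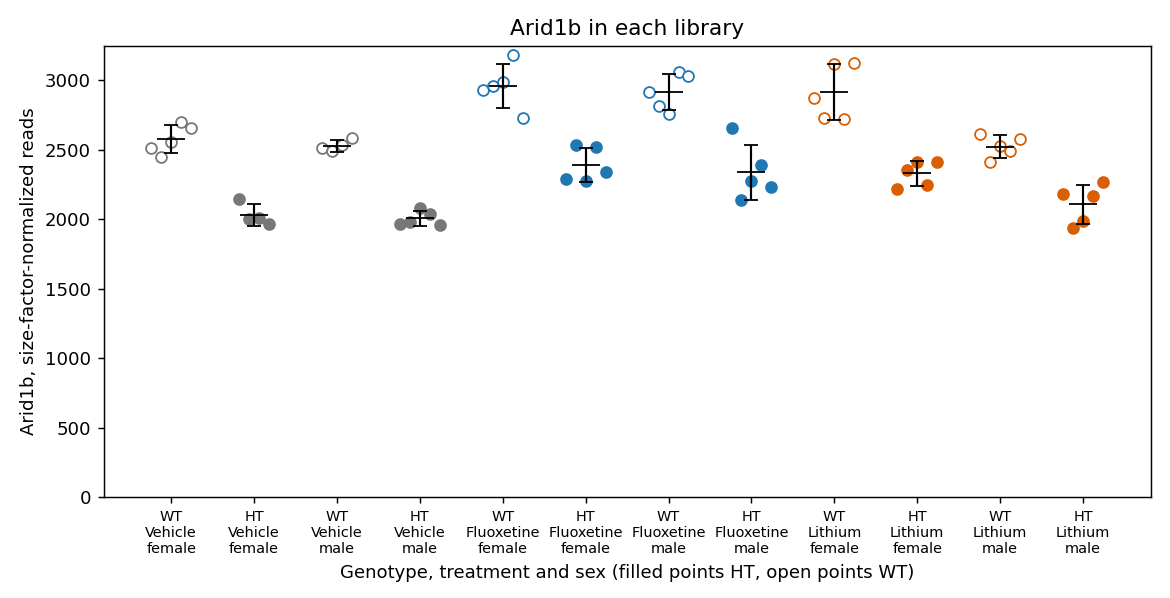
Arid1b normalised read count (vertical axis) in each library of the 12 groups (horizontal axis), with open points for WT, filled points for HT and bars for the mean ± SD of each group. Vehicle HT libraries lie between 1962 and 2143 and vehicle WT libraries between 2450 and 2700.

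The genotype comparison asked which transcripts differed between HT and WT cortex without a drug (9 HT and 9 WT vehicle libraries, both sexes). Arid1b itself fell by 0.34 on the log2 scale (SE 0.037, adjusted p = 3.1e-08), to 0.791 of the WT level. Of the 16632 genes tested, 4 were higher and 4 lower in HT, and 7 of these 8 are named here. Trim54, a muscle-enriched ubiquitin ligase gene, rose by 1.12 (SE 0.21, adjusted p = 0.012), from 9.76 ± 4.14 to 22.1 ± 7.64 normalised reads (SD, n = 9 each). Megf6 rose by 0.62 (SE 0.12, adjusted p = 0.014). Xdh, which encodes xanthine dehydrogenase, rose by 0.73 (SE 0.15, adjusted p = 0.031). Smad3, a transcription factor of transforming growth factor beta signalling, rose by 0.22 (SE 0.045, adjusted p = 0.031). Igfn1 fell by 0.81 on the log2 scale (SE 0.17) and BC006965 by 0.50 (SE 0.11), each with adjusted p = 0.049. With a drug, the HT and WT means of Trim54 (16.7 and 13.8 with fluoxetine, 16.1 and 14.6 with lithium) lay closer together. Megf6 had 243 and 245 with fluoxetine and 238 and 194 with lithium, and Xdh 74.1 and 66.3, and 56.3 and 61.4. Smad3 stayed higher in HT (2410 and 2110, 2140 and 2010). Igfn1 (437 and 561, 327 and 577) and BC006965 (79.1 and 85.5, 70.7 and 83.3) stayed lower. HT was not tested against WT within a drug. By limma, 1164 genes had an unadjusted p under 0.05, where 832 would be expected by chance.

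Between the genotypes 7 of the 39 gene lists were called, 6 higher and 1 lower in HT. The 81 cytosolic ribosomal protein genes lay higher in HT as a list, with a median log2 fold change of 0.08 and none passing alone (adjusted p = 2.2e-07; adjusted p = 0.96 with an estimated correlation). Ribosomal protein genes share reads with processed pseudogenes, so single members are uncertain. The 23 glucocorticoid response genes lay higher by a median of 0.18 (adjusted p = 2.4e-05; adjusted p = 0.93 with an estimated correlation). None of these passed over all genes, and 2 rose and 1 fell adjusted over the list alone. Fkbp5, a chaperone induced by glucocorticoids, had a log2 fold change of 0.77 (SE 0.19, adjusted p = 0.098), and Hif3a had 0.78 (SE 0.21, adjusted p = 0.17). The 32 oligodendrocyte and myelin genes lay lower by a median of -0.16 (adjusted p = 0.013; adjusted p = 0.96 with an estimated correlation). Smaller shifts up were called for 26 endoplasmic reticulum stress genes (median 0.02, adjusted p = 0.017), 24 deep layer neuron genes (0.09, adjusted p = 0.033), 76 oxidative phosphorylation genes (0.04, adjusted p = 0.036) and 25 immature neuron genes (0.07, adjusted p = 0.048). With an estimated correlation these had adjusted p = 0.96, 0.96, 0.99 and 0.96, and no member passed over all genes (1 deep layer gene rose adjusted over the list alone). Olfactory area markers, which mark tissue next to the dissected region, had a median of 0.47 between the genotypes (adjusted p = 0.084). Their marker Cdhr1 ranged from 120 to 4664 normalised reads across the 58 libraries. With the olfactory marker score as a covariate the myelin list (adjusted p = 0.12, against 1.1e-06 to 0.96 over all alternatives) and the immature neuron list (0.6, against 0.0065 to 0.96) no longer passed.

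The genotype count rested on single libraries. It was 1 without WT vehicle male 4, 3 without HT vehicle female 2, HT vehicle male 2 or 3, WT vehicle female 1, 4 or 5 or WT vehicle male 3, 4 without HT vehicle male 1 or WT vehicle female 2, and 5 without WT vehicle female 3 or WT vehicle male 1 or 2. It was 17 without the 3 libraries picked by eye. It was 3 after a correction of each library for GC content and gene length. That ended calls that included those of Xdh (log2 fold change 0.72), Smad3 (0.20), Igfn1 (-0.84) and BC006965 (-0.49) and of the immature neuron list (median 0.06). Trim54 and Megf6 lost their calls without WT vehicle male 4, and both, with Xdh, when the vehicle libraries were fitted alone. By edgeR 6 genes passed, with Igfn1 (-0.80) and BC006965 (-0.50) not among them, and quantile normalisation ended the calls of the oxidative phosphorylation and immature neuron lists, library weights those of the deep layer, oxidative phosphorylation and endoplasmic reticulum stress lists, and the replicate block that of the immature neuron list.

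The next comparison asked which transcripts differed with fluoxetine in HT cortex (10 fluoxetine and 9 vehicle libraries). Of the 39 gene lists 13 were called, 7 higher and 6 lower, and with an estimated correlation none of them passed (smallest adjusted p = 0.13). Nova2, a neuronal splicing regulator (ENSMUSG00000030411, chromosome 7, 18925888 to 18965319), rose by 0.42 (SE 0.034, adjusted p = 4.9e-13), from 3510 ± 177 (SD, n = 9) to 4700 ± 110 normalised reads (SD, n = 10), and by 0.175 after the GC and length correction. The synaptic vesicle protein gene Syn1 rose by 0.44 (SE 0.038) and the hexokinase gene Hk1 by 0.43 (SE 0.038), each with adjusted p = 2.4e-12. Atn1, Os9, Wnk2, Cc2d1a, Mef2d and Ctnnd2 also rose, by 0.31 to 0.45. Hibadh, an enzyme of valine breakdown, fell by 0.38 on the log2 scale (SE 0.034, adjusted p = 3.1e-12), and Itm2a fell by 0.61 (SE 0.058, adjusted p = 1e-11). Pnrc2, Laptm4a, Zfand6, Bbip1, Paip2, Selenof, Rpl27 and Rpl22 also fell, by 0.26 to 0.62 on the log2 scale. After that correction Syn1, Os9, Wnk2, Cc2d1a and Mef2d had 0.122 to 0.263 and Hibadh, Zfand6, Bbip1, Paip2 and Selenof -0.295 to -0.0717, each over 1.5 times smaller but still passing. Arid1b rose by 0.23 (SE 0.036, adjusted p = 1.4e-06), but lay at -0.05 after the GC and length correction.

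Synaptic and chromatin lists lay higher with fluoxetine in HT. Of 60 genes linked to autism risk, 38 rose, 2 fell and 20 did not pass (40 and 3 adjusted over the list alone), with a median log2 fold change of 0.22 (adjusted p = 1.6e-10; adjusted p = 0.93 with an estimated correlation). Examples were Nlgn3, a neuronal adhesion gene (0.34, SE 0.032), Tsc1 (0.26, SE 0.027) and the postsynaptic scaffold gene Shank2 (0.37, SE 0.042). Of 50 glutamate receptor and postsynaptic genes, 29 rose, 1 fell and 20 did not pass (30 and 2 adjusted over the list alone), with a median of 0.22 (adjusted p = 5e-10; adjusted p = 0.13 with an estimated correlation). Grin1, the obligatory NMDA receptor subunit, rose by 0.41 (SE 0.037) and Dlgap4 by 0.33 (SE 0.029). Of 44 synaptic vesicle and release genes, 19 rose, 1 fell and 24 did not pass (19 and 1 adjusted over the list alone; median 0.16, adjusted p = 2.9e-05; adjusted p = 0.96 with an estimated correlation), among them Dnm1 (0.48, SE 0.044) and Bsn (0.54, SE 0.052). Of 41 voltage-gated ion channel genes, 21 rose, none fell and 20 did not pass (22 and 0 adjusted over the list alone; median 0.20, adjusted p = 5.3e-05; adjusted p = 0.93 with an estimated correlation), among them Cacna1a (0.40, SE 0.047). Of 30 BAF complex subunits, 13 rose, 2 fell and 15 did not pass (16 and 2 adjusted over the list alone; median 0.12, adjusted p = 0.0018; adjusted p = 0.93 with an estimated correlation), among them Smarcc2 (0.35, SE 0.031), Bicra (0.50, SE 0.051) and Arid1a (0.35, SE 0.042). Of 19 circadian clock genes, 9 rose, 2 fell and 8 did not pass (10 and 2 adjusted over the list alone; median 0.18, adjusted p = 0.04; adjusted p = 0.96 with an estimated correlation), among them Npas2 (0.44, SE 0.052) and Per2 (0.43, SE 0.085). Of 30 Wnt and beta-catenin targets, 9 rose, none fell and 21 did not pass (9 and 0 adjusted over the list alone; median 0.19, adjusted p = 0.049; adjusted p = 0.93 with an estimated correlation). Among these Lef1 rose by 0.53 (SE 0.096) and Axin2 by 0.26 (SE 0.049). Nlgn3, Tsc1, Shank2, Grin1, Dlgap4, Dnm1, Bsn, Bicra and Arid1a had 0.151 to 0.302 after the GC and length correction, each over 1.5 times smaller but still passing.

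Lists for ribosomes, respiration and sterols lay lower with fluoxetine in HT. Of 81 ribosomal protein genes, none rose, 46 fell and 35 did not pass (0 and 49 adjusted over the list alone), with a median of -0.23 (adjusted p = 8.4e-11; adjusted p = 0.96 with an estimated correlation). Of 76 oxidative phosphorylation genes, 1 rose, 35 fell and 40 did not pass (1 and 38 adjusted over the list alone; median -0.15, adjusted p = 1.6e-06; adjusted p = 0.96 with an estimated correlation), and cytochrome c (Cycs) fell by 0.33 on the log2 scale (SE 0.046). Of 27 cholesterol synthesis and uptake genes, none rose, 16 fell and 11 did not pass (0 and 16 adjusted over the list alone), with a median of -0.22 (adjusted p = 2.6e-07; adjusted p = 0.93 with an estimated correlation). Idi1, which makes an isoprenoid precursor of sterols (ENSMUSG00000058258, chromosome 13, 8885501 to 8892451), fell by 0.57 on the log2 scale (SE 0.062, adjusted p = 2.6e-10). It went from 2050 ± 137 (SD, n = 9) to 1380 ± 110 normalised reads (SD, n = 10). Msmo1 fell by 0.50 (SE 0.066), Sqle by 0.37 (SE 0.049) and Fdps by 0.40 (SE 0.055) on the log2 scale. Of 32 oligodendrocyte and myelin genes, none rose, 3 fell and 29 did not pass (0 and 1 adjusted over the list alone; median -0.34, adjusted p = 0.037; adjusted p = 0.99 with an estimated correlation), with Aspa at -0.60 (SE 0.18) and Ugt8a at -0.65 (SE 0.21). Of 29 interferon response genes, 1 rose, 8 fell and 20 did not pass (1 and 8 adjusted over the list alone; median -0.18, adjusted p = 0.04; adjusted p = 0.96 with an estimated correlation), with B2m at -0.32 (SE 0.069) and Isg15 at -0.59 (SE 0.16). Of 26 proliferation genes, none rose, 5 fell and 21 did not pass (0 and 4 adjusted over the list alone; median -0.29, adjusted p = 0.049; adjusted p = 0.96 with an estimated correlation), with Pcna at -0.13 (SE 0.041). The 19 serotonin system genes did not move as a list (median -0.15, adjusted p = 0.34). Among them 2 rose and 4 fell, Maoa, which breaks down serotonin, by 0.19 (SE 0.041) and Tph2, which makes it in neurons, by 0.92 (SE 0.25) on the log2 scale. Cycs (-0.191), Idi1 (-0.365) and Maoa (-0.12) were over 1.5 times smaller after the GC and length correction, and Aspa (-0.41), Ugt8a (-0.565), B2m (-0.121) and Pcna (0.0576) no longer passed.

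In total 3026 genes were higher and 2965 lower with fluoxetine in HT by limma, and the median size of the called changes was 0.245 on the log2 scale. Fold changes followed the GC content of the transcripts across genes (Spearman's rho 0.445, genes not being independent replicates). The slope of expression over GC content was negative in all 18 vehicle libraries (-0.19 to -0.025 log2 per 10 points) and positive in 17 of the 20 fluoxetine libraries. After the GC and length correction 4757 genes were called, 3602 of them called before in the same direction. The Wnt and proliferation lists no longer passed (medians 0.09 and -0.24), and quantile normalisation ended the calls of these and of the myelin, vesicle, clock and interferon lists. The Wnt list also lost its call with library weights, the replicate block or 3 libraries left out, the proliferation list with the block or the olfactory covariate, the interferon list with weights and the clock list with the olfactory covariate.

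**Figure D2:**
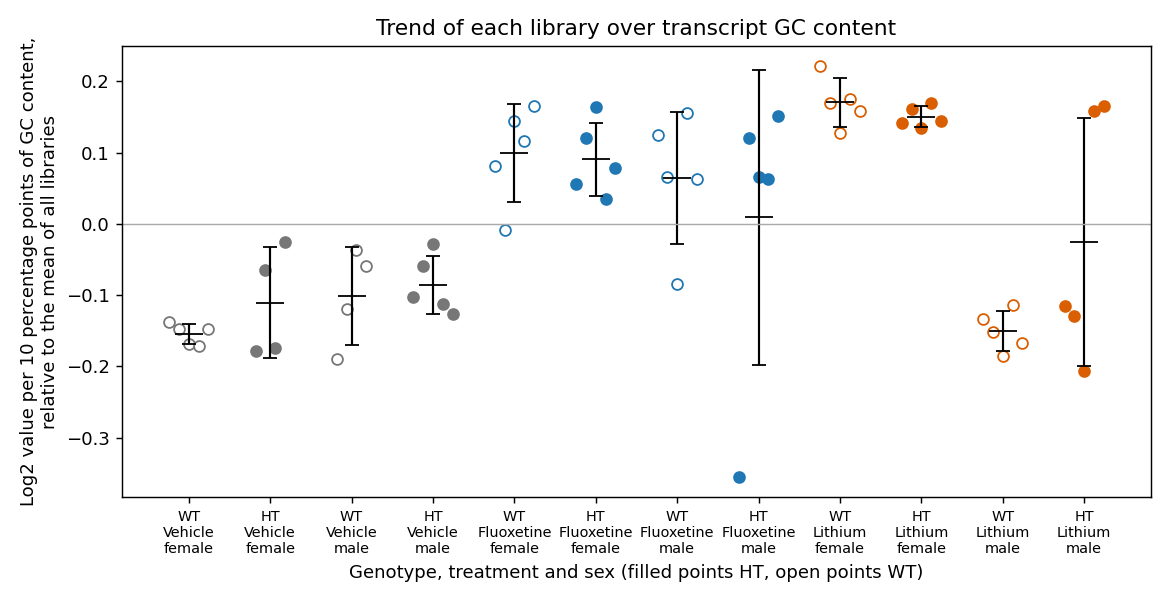
Slope of log2 expression over transcript GC content (vertical axis, log2 per 10 percentage points) in each library, by treatment and sex (horizontal axis), with open points for WT and filled points for HT. All 18 vehicle libraries lie below 0, all 10 lithium females lie between 0.127 and 0.221, and 8 of 10 lithium males lie below 0.

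Fluoxetine in WT cortex was compared with vehicle in the same way (10 and 9 libraries). Nova2 rose by 0.39 (SE 0.034, adjusted p = 1.9e-11), and by 0.114 after the GC and length correction. The lipoprotein receptor gene Lrp1 rose by 0.46 and the presynaptic adhesion gene Nrxn2 by 0.43 (SE 0.046 and 0.043, adjusted p = 2.7e-10 for both). Cherp, Os9, Wipf3, Ttyh3, Sgsm1 and Upf1 rose by 0.32 to 0.61. Idi1 fell by 0.55 on the log2 scale (SE 0.062, adjusted p = 2.5e-09) and Erg28, whose product joins the sterol synthesis enzymes, by 0.39 (SE 0.045, adjusted p = 4.4e-09). Bbip1, Laptm4a, Zfand6, Selenof, Bud31, Btbd1 and Mettl9 fell by 0.31 to 0.40 on the log2 scale. After that correction Nrxn2, Os9, Ttyh3, Sgsm1 and Upf1 had 0.101 to 0.28 and Idi1, Bbip1, Zfand6, Selenof, Btbd1 and Mettl9 -0.287 to -0.122, each over 1.5 times smaller but still passing. Paip2 fell by 0.24 (SE 0.026), but lay at -0.01 after the GC and length correction and no longer passed. Arid1b rose by 0.20 (SE 0.036, adjusted p = 1.2e-05), and lay at -0.11 after that correction.

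Of 27 cholesterol genes, none rose, 16 fell and 11 did not pass with fluoxetine in WT (0 and 16 adjusted over the list alone), with a median of -0.26 (adjusted p = 3.1e-06; adjusted p = 0.93 with an estimated correlation). Sqle fell by 0.38 (SE 0.049), Msmo1 by 0.51 (SE 0.066) and Stard4 by 0.48 (SE 0.063) on the log2 scale. The mean cholesterol gene score lay below 0, the mean of all libraries, in all 20 fluoxetine libraries of both genotypes. Of 29 perineuronal net and extracellular matrix genes, 14 rose, 1 fell and 14 did not pass (15 and 1 adjusted over the list alone; median 0.21, adjusted p = 0.00029; adjusted p = 0.93 with an estimated correlation), among them Ncan (0.36, SE 0.037) and the fibronectin gene Fn1 (0.53, SE 0.068). Of 60 autism risk genes, 29 rose, 7 fell and 24 did not pass (30 and 7 adjusted over the list alone; median 0.13, adjusted p = 0.00029; adjusted p = 0.96 with an estimated correlation), among them Tsc2 (0.28, SE 0.031). Of 23 glucocorticoid response genes, 11 rose, 2 fell and 10 did not pass (11 and 2 adjusted over the list alone; median 0.23, adjusted p = 0.032; adjusted p = 0.96 with an estimated correlation). Hif3a rose by 1.32 (SE 0.20), the lipid droplet gene Plin4 by 1.63 (SE 0.34) and Zbtb16 by 0.67 (SE 0.14), while Nr3c1, the glucocorticoid receptor gene, fell by 0.34 on the log2 scale (SE 0.068).

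Of 50 glutamate receptor and postsynaptic genes, 24 rose, 6 fell and 20 did not pass with fluoxetine in WT (25 and 6 adjusted over the list alone; median 0.18, adjusted p = 2.9e-05; adjusted p = 0.69 with an estimated correlation). Nlgn2, an adhesion gene of inhibitory synapses, rose by 0.34 (SE 0.035) and Grin1 by 0.33 (SE 0.037). Of 30 BAF subunits, 15 rose, 2 fell and 13 did not pass (15 and 2 adjusted over the list alone; median 0.14, adjusted p = 0.004; adjusted p = 0.96 with an estimated correlation). Of 44 vesicle genes, 16 rose, 5 fell and 23 did not pass (16 and 5 adjusted over the list alone; median 0.08, adjusted p = 0.015; adjusted p = 0.96 with an estimated correlation). Of 41 ion channel genes, 18 rose, 4 fell and 19 did not pass (18 and 4 adjusted over the list alone; median 0.13, adjusted p = 0.032; adjusted p = 0.96 with an estimated correlation). These 4 lists no longer passed after the GC and length correction, with medians of 0.04, 0.03, 0.01 and 0.01. The 19 serotonin genes had a median of -0.09 (adjusted p = 0.42), and Maoa fell by 0.35 on the log2 scale (SE 0.041, adjusted p = 5.9e-09). Nlgn2 (0.102), Grin1 (0.0906), Ncan (0.121) and Maoa (-0.205) were over 1.5 times smaller after that correction but still passed.

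By limma, 3059 genes were higher and 3360 lower with fluoxetine in WT, and fold changes followed GC content with a Spearman's rho of 0.628 across genes. The GC and length correction lowered the number called to 3622, of which 2614 had been called before in the same direction. Quantile normalisation ended the calls of the vesicle and ion channel lists.

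**Figure D3:**
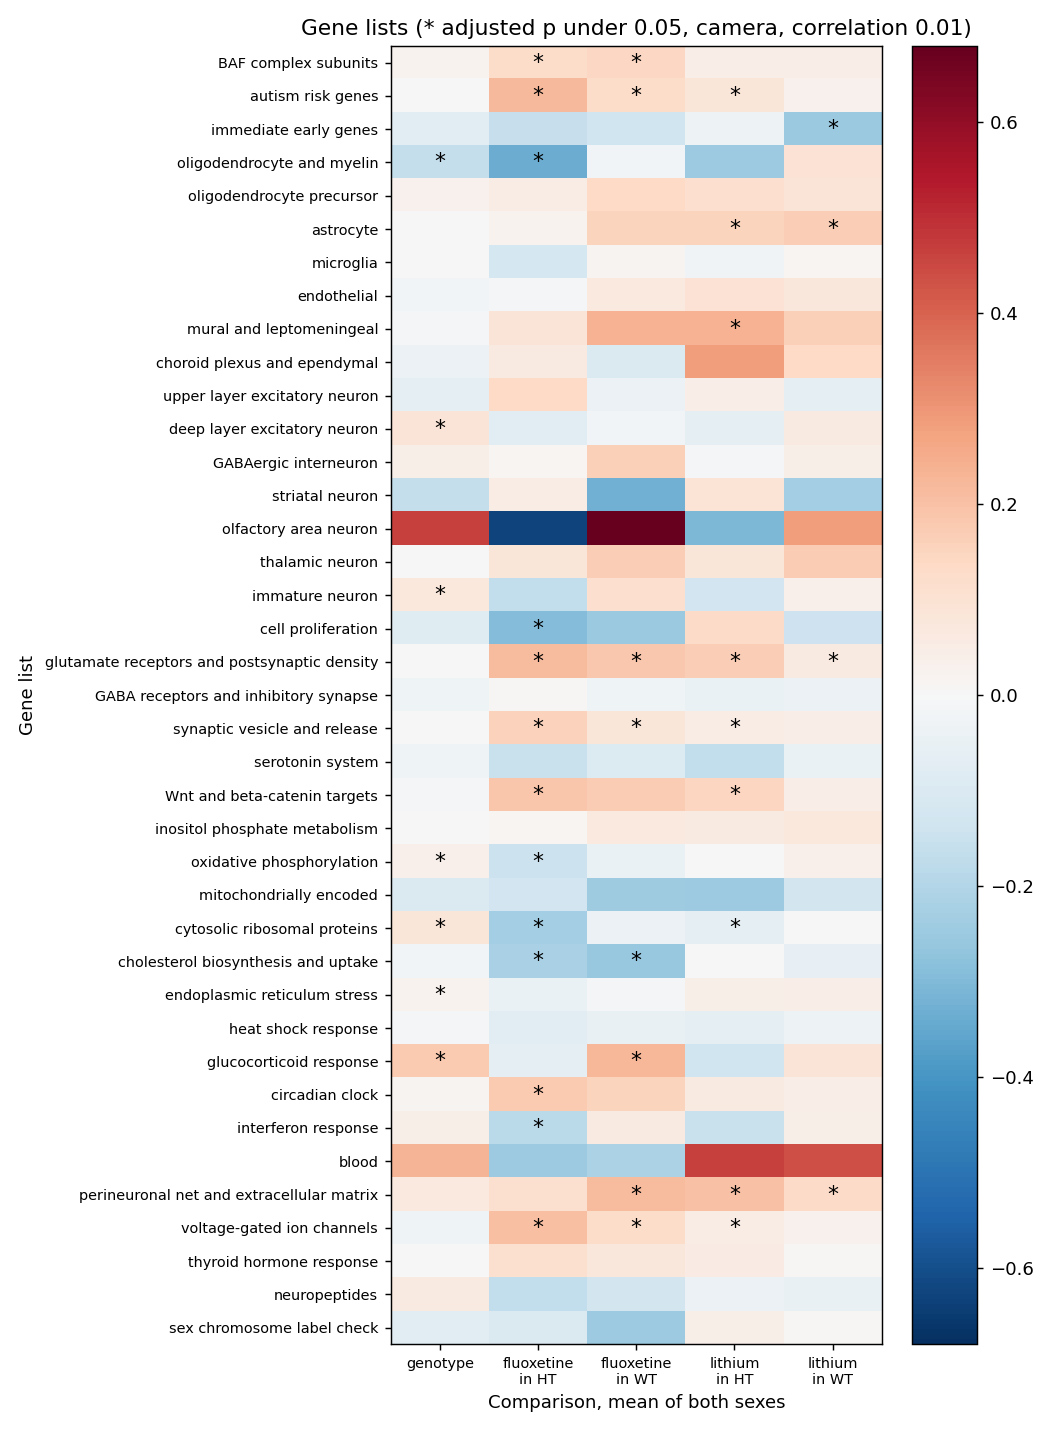
Median log2 fold change (colour) of the members of each of 39 gene lists (vertical axis) in the 5 main comparisons (horizontal axis), with a star where the list passed at the preset correlation. Cholesterol genes are lower with fluoxetine in both genotypes (-0.22 and -0.26), and no star holds with an estimated correlation.

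Lithium in HT cortex was compared with vehicle in 10 and 9 libraries. Ints1, a subunit of the Integrator complex of RNA processing (ENSMUSG00000029547, chromosome 5, 139751282 to 139775674), rose by 0.42 (SE 0.043, adjusted p = 4.7e-09). Ncan, a proteoglycan of the brain's extracellular matrix, rose by 0.36 (SE 0.037, adjusted p = 4.7e-09), and Vgf, which encodes a neuropeptide precursor, rose by 0.65 (SE 0.079, adjusted p = 2.9e-07). Lrp1, Snd1, Myo18a, Nlgn2 and Ttyh3 rose by 0.27 to 0.37. In females Ints1 had 0.60 and Ncan 0.56, and in males they had 0.24 and 0.16. Triqk fell by 0.44 (SE 0.062, adjusted p = 2.2e-06), and 2810013P06Rik, Fam45a, Immp1l, Pnrc2, Cdk19, Rsrc1 and Rps3a1 fell by 0.21 to 0.37 on the log2 scale. Ncan, Vgf, Myo18a, Nlgn2 and Ttyh3 had 0.0901 to 0.42 after the GC and length correction, and Triqk, Fam45a, Immp1l, Pnrc2 and Rsrc1 -0.22 to -0.14, each over 1.5 times smaller but still passing. Nova2 (0.27), Paip2 (-0.20) and Eif3e (-0.28) were called too, but had 0.06, -0.03 and -0.09 after it and no longer passed. Arid1b rose by 0.13 (SE 0.036, adjusted p = 0.0049), and lay at -0.10 after that correction.

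Matrix, mural and Wnt lists lay higher with lithium in HT. Of 29 perineuronal net and matrix genes, 9 rose, none fell and 20 did not pass (9 and 1 adjusted over the list alone; median 0.20, adjusted p = 0.00046; adjusted p = 0.93 with an estimated correlation), among them Fn1 (0.43, SE 0.068) and Lama5 (0.43, SE 0.068). Of 24 mural and leptomeningeal genes, 10 rose, none fell and 14 did not pass (11 and 0 adjusted over the list alone; median 0.24, adjusted p = 0.0015; adjusted p = 0.96 with an estimated correlation), among them the pericyte genes Pdgfrb (0.38, SE 0.067) and Cspg4 (0.40, SE 0.071) and the collagen gene Col1a1 (0.57, SE 0.14). The blood list (median 0.46, adjusted p = 0.1), the endothelial list (0.10, adjusted p = 0.084) and the choroid plexus list (0.29, adjusted p = 0.19) did not pass. HT lithium male 5 had 9013 normalised reads of Ttr, where the other 57 libraries had at most 182, and with 3 libraries left out, this among them, the mural list still passed (adjusted p = 0.0014, against 0.00054 to 0.96 over all alternatives). Of 30 Wnt and beta-catenin targets, a pathway restrained by a kinase that lithium inhibits, 8 rose, 1 fell and 21 did not pass (9 and 1 adjusted over the list alone; median 0.14, adjusted p = 0.0053; adjusted p = 0.69 with an estimated correlation). Sp5, a direct target of beta-catenin, rose by 1.17 (SE 0.24), Apcdd1 by 0.39 (SE 0.095) and Znrf3 by 0.25 (SE 0.036), while Ctnnb1, the beta-catenin gene, fell by 0.18 on the log2 scale (SE 0.040). Pdgfrb (0.228), Cspg4 (0.201) and Znrf3 (0.152) were over 1.5 times smaller after the GC and length correction but still passed. Of 50 glutamate receptor and postsynaptic genes, 21 rose, 2 fell and 27 did not pass (25 and 2 adjusted over the list alone; median 0.17, adjusted p = 1.6e-06; adjusted p = 0.58 with an estimated correlation). Of 60 autism risk genes, 18 rose, 3 fell and 39 did not pass (21 and 6 adjusted over the list alone; median 0.08, adjusted p = 0.0015; adjusted p = 0.96 with an estimated correlation). Of 81 ribosomal protein genes, 3 rose, 19 fell and 59 did not pass (3 and 19 adjusted over the list alone; median -0.06, adjusted p = 0.013; adjusted p = 0.99 with an estimated correlation).

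A further 3 lists were called with lithium in HT and were lost after the GC and length correction. Of 41 ion channel genes, 10 rose, none fell and 31 did not pass (10 and 0 adjusted over the list alone; median 0.05, adjusted p = 0.017; adjusted p = 0.96 with an estimated correlation). Of 44 vesicle genes, 11 rose, 2 fell and 31 did not pass (11 and 2 adjusted over the list alone; median 0.05, adjusted p = 0.037; adjusted p = 0.96 with an estimated correlation). Of 27 astrocyte genes, 8 rose, 2 fell and 17 did not pass (10 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.048; adjusted p = 0.96 with an estimated correlation), and the glial transcription factor gene Sox9 rose by 0.54 (SE 0.092). After the correction the medians were 0.02, 0.003 and 0.09. By limma, 1931 genes were higher and 1921 lower with lithium in HT. The correction lowered the number called to 1483, of which 1033 had been called before in the same direction. Quantile normalisation ended the calls of these 3 lists and of the autism list, and leaving out the 3 libraries picked by eye, library weights and the replicate block each ended that of the astrocyte list. The GC slope averaged 0.16 in the 10 lithium females of both genotypes and -0.0878 in the 10 lithium males.

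With lithium in WT cortex 10 of 34 immediate early genes, which neuronal activity induces rapidly, were lower, and the list did not pass with an estimated correlation (adjusted p = 0.93). Nr4a1, an orphan nuclear receptor gene (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795), fell by 0.93 on the log2 scale (SE 0.16, adjusted p = 0.00031). It went from 3230 ± 386 (SD, n = 9) to 1750 ± 445 normalised reads (SD, n = 10). Btg2 fell by 0.94 (SE 0.15, adjusted p = 8.2e-05), the phosphatase gene Dusp1 by 0.87 (SE 0.14, adjusted p = 0.00017), Trib1 by 0.62 (SE 0.094, adjusted p = 6.1e-05), Csrnp1 by 0.76 (SE 0.12, adjusted p = 8.1e-05) and Ier2 by 0.81 (SE 0.14, adjusted p = 0.00043) on the log2 scale. These 6 genes were lower in both sexes. None of the 34 immediate early genes rose and 24 did not pass (0 rose and 12 fell adjusted over the list alone), with a median of -0.25 (adjusted p = 1.1e-06; adjusted p = 0.93 with an estimated correlation). In HT the same list had a median of -0.04 with lithium (adjusted p = 0.85), with 3 genes higher and 2 lower, and no gene passed the test of the difference between the genotypes. Memo1, 1700016P03Rik, St8sia4 and Gk5 also fell, by 0.28 to 1.66 on the log2 scale (Memo1 -0.164 and St8sia4 -0.25 after the GC and length correction).

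Genes that rose with lithium in WT included Sgsm1 (0.32, SE 0.042, adjusted p = 6.5e-06), Ints1 (0.33, SE 0.043, adjusted p = 6.5e-06) and the lysosomal genes Grn (0.33, SE 0.048, adjusted p = 5.4e-05) and Ctsa (0.29, SE 0.044, adjusted p = 6.1e-05). In females and males Ints1 had 0.562 and 0.0882, Grn 0.547 and 0.105, Rab11fip3 0.407 and 0.0444, and Memo1 -0.503 and -0.0639. Castor2, Zhx3, Rab11fip3 and Pik3ip1 rose by 0.23 to 0.45 (Rab11fip3 by 0.114 after the GC and length correction). Os9 rose by 0.19 (SE 0.030), but lay at 0.09 after the GC and length correction and no longer passed. Arid1b had 0.09 (SE 0.036, adjusted p = 0.1) and did not pass. It passed with 3 libraries left out (adjusted p = 0.049, against 0.049 to 0.38 over all alternatives). Of 27 astrocyte genes, 6 rose, none fell and 21 did not pass (12 and 0 adjusted over the list alone; median 0.17, adjusted p = 0.00029; adjusted p = 0.96 with an estimated correlation), among them Htra1 (0.31, SE 0.076). Of 29 perineuronal net and matrix genes, 7 rose, none fell and 22 did not pass (7 and 0 adjusted over the list alone; median 0.13, adjusted p = 0.0013; adjusted p = 0.93 with an estimated correlation), among them Ncan (0.20, SE 0.037) and Fn1 (0.31, SE 0.068). Of 50 glutamate receptor and postsynaptic genes, 11 rose, none fell and 39 did not pass (15 and 4 adjusted over the list alone; median 0.06, adjusted p = 0.025; adjusted p = 0.96 with an estimated correlation), and after the correction the list lay lower, at -0.02, without passing. The 25 inositol phosphate genes, whose pathway holds a target of lithium, had a median of 0.07 (adjusted p = 0.11), and Itpk1 rose by 0.25 (SE 0.063, adjusted p = 0.008). It had 0.167 after the correction, and Ncan had 0.0749 and no longer passed.

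By limma, 996 genes were higher and 839 lower with lithium in WT, and fold changes followed GC content with a Spearman's rho of 0.637 across genes. The number called was 445 after the GC and length correction (318 of them called before in the same direction), 3219 with the 3 libraries picked by eye left out, and 1046 without WT vehicle male 1. Quantile normalisation and library weights ended the call of the glutamate receptor list.

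The sexes were compared within each genotype. With lithium, far more genes passed in females than in males. In HT 4064 genes passed in females (2141 higher, 1923 lower) and 2 in males, Cd248, a gene of pericytes and stroma (0.65, SE 0.11, adjusted p = 0.0056), and the elastin gene Eln (0.70, SE 0.14, adjusted p = 0.036). In HT females Ncan rose by 0.56, Ints1 by 0.60, Nova2 by 0.47 (0.158 after the GC and length correction) and Lrp1 by 0.57, and 2810013P06Rik, Paip2, Rps3a1 and Eif3e fell by 0.28 to 0.49 on the log2 scale. In HT males Gas2 (-0.36, adjusted p = 0.069) and Itm2a (-0.34, adjusted p = 0.11) did not pass. In WT 5710 genes passed in females (2785 higher, 2925 lower), led by Ints1 (0.56, SE 0.059), Rab11fip3 (0.41) and Lrp1 (0.53) upward and Srsf7 (-0.53), Orc4 (-0.55), Memo1 (-0.50) and Paip2 (-0.28) downward. After the GC and length correction Paip2 and Eif3e in HT females had -0.02 and -0.12 and Paip2 in WT females 0.01, and none of these passed. Ncan (0.293) and Rps3a1 (-0.188) in HT females and Ints1 (0.308), Rab11fip3 (0.165), Lrp1 (0.3), Srsf7 (-0.229), Orc4 (-0.127) and Memo1 (-0.243) in WT females were over 1.5 times smaller but still passed. In WT males 14 genes passed. Gm17249 (1.57), Pkp2 (1.33), the macrophage receptor gene Cd163 (1.36) and Xdh (1.01) were higher. Ier2 (-1.17), Csrnp1 (-0.94), Trib1 (-0.70) and Nr4a1 (-1.19) were lower, with adjusted p from 0.0036 to 0.028.

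The difference between the sexes was itself tested. For lithium in HT 4 genes were higher and 93 lower in males relative to females, among them Lzts1 (-0.43, SE 0.069, adjusted p = 0.0011), Nova2 (-0.40), Gpc1 (-0.50), Myh9 (-0.48), Zfp422 (0.41), Maip1 (0.37), Asf1a (0.56) and Zcrb1 (0.38). For lithium in WT 1585 genes were higher and 1525 lower, among them Ogn (1.76, SE 0.29), Zfp386 (0.68), Orc4 (0.61), Paip2 (0.31), Lrp1 (-0.54), Hgs (-0.54), Cul9 (-0.49) and Mapk8ip3 (-0.45), with adjusted p from 0.00052 to 0.00054. These differences followed GC content with a Spearman's rho of -0.641 in HT and -0.754 in WT across genes. The GC slope was higher in lithium females than in lithium males by 0.248 (0.16 against -0.0878, n = 10 each, 2-sided permutation test, p = 0.00062, adjusted p = 0.00093 over 3 tests), and depth by 4.38 M reads (33.2 against 28.8, permutation p = 0.01, adjusted p = 0.01). After the GC and length correction 6 genes differed in HT and 176 in WT, of those named here only Lzts1 (-0.378), Gpc1 (-0.33), Ogn (1.3) and Zfp386 (0.409), and with the GC slope as a covariate 4 and 0. HT lithium males 4 and 5 had GC slopes of 0.158 and 0.166, within the range of the lithium females.

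With fluoxetine, many genes passed in either sex. In HT 3574 genes passed in females (1987 higher, 1587 lower) and 3124 in males (1567 higher, 1557 lower). In WT 4412 passed in females (2070 higher, 2342 lower) and 2945 in males (1380 higher, 1565 lower). Nova2 rose in each of the 4 sets, by 0.46 and 0.38 in HT females and males and by 0.41 and 0.38 in WT females and males, and after the GC and length correction by 0.192, 0.158, 0.116 and 0.113. Atn1, Mef2d and Syn1 in HT females, Os9 and Setd1a in HT males, Os9, Cc2d1a and Nrxn2 in WT females, and Sgsm1, Wipf3 and Nectin1 in WT males rose by 0.32 to 0.87. Laptm4a fell by 0.36 and 0.37 in HT females and males and by 0.35 in WT females on the log2 scale. Zfand6, Pnrc2 and 1110059E24Rik in HT females, Hibadh, Zfand6 and Itm2a in HT males, Paip2, Bbip1 and Zfand6 in WT females, and Cdc16, Smim8, Bbip1 and Fopnl in WT males fell by 0.26 to 0.61 on the log2 scale. Cc2d1a, Paip2 and Bbip1 in WT females and Fopnl in WT males no longer passed after the GC and length correction (0.12, -0.03, -0.12 and -0.16). Atn1 (0.281), Mef2d (0.2), Syn1 (0.3), 1110059E24Rik (-0.337) and Zfand6 (-0.265) in HT females, Os9 (0.197), Nrxn2 (0.176) and Zfand6 (-0.221) in WT females and Cdc16 (-0.167) and Bbip1 (-0.137) in WT males were over 1.5 times smaller but still passed. No gene differed between the sexes in its response to fluoxetine by limma, with 496 at an unadjusted p under 0.05 in HT, 355 in WT and none by edgeR in either. Pcolce2 (0.93) and Snhg3 (-0.93) in HT, and Phldb2 (0.87) and Gm20691 (-4.65, a predicted gene) in WT, ranked high without passing (adjusted p = 1).

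**Figure D4:**
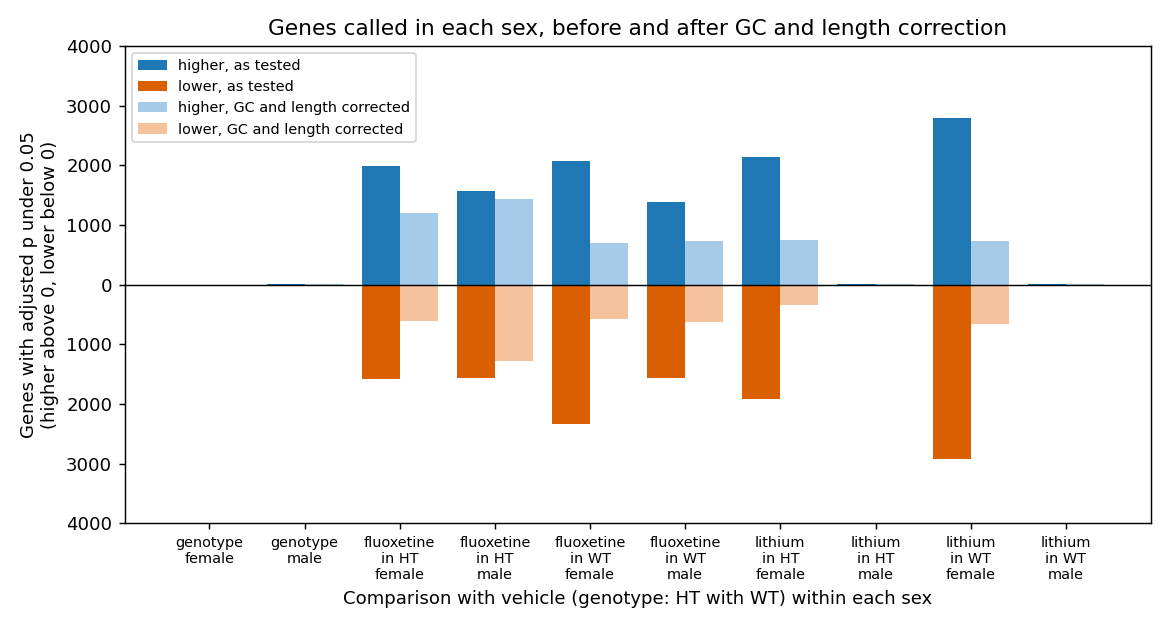
Number of genes higher and lower (vertical axis) in each comparison within one sex (horizontal axis), as tested and after correction of each library for GC content and gene length. With lithium 4064 genes passed in HT females and 2 in HT males as tested, and 1089 and 4 after the correction.

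Between the genotypes without a drug, Arid1b fell by 0.34 in females and by 0.33 in males on the log2 scale (SE 0.052 each, adjusted p = 0.00037 and 0.00072). In females Bche, which encodes butyrylcholinesterase, also fell, by 0.80 on the log2 scale (SE 0.15, adjusted p = 0.029). In males Gm17249 (1.37, SE 0.26, adjusted p = 0.029), Lncpint (1.12, SE 0.22, adjusted p = 0.035) and Xdh (1.04, SE 0.21, adjusted p = 0.035) rose. The noncoding genes Gm17249 and Lncpint are uncertain, since the strand setting of the counting is not given in the sources used here. No gene differed between the sexes in its genotype effect by limma (513 at an unadjusted p under 0.05, none by edgeR), and Gm17249 (1.62), Dnhd1 (0.73), Gm17916 (-1.67) and Gm49317 (-1.14) ranked high without passing (adjusted p = 1). The male count of 4 was 1 by edgeR, and fell to 1 without HT vehicle male 1, 2 or 3 or WT vehicle male 2 and to 2 without WT vehicle male 1 or 3. The female count of 2 fell to 1 without HT vehicle female 1, 2 or 4 or WT vehicle female 1, 2, 3 or 4. Arid1b lost its call in females when the vehicle females were fitted alone (adjusted p = 0.15, against 7.3e-06 to 0.15 over all alternatives).

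Several counts within males depended on single libraries. For lithium in HT males the count of 2 was 0 without HT lithium male 4 or 5, 27 without HT lithium male 3, 13 without HT lithium male 1, and 1 without HT lithium male 2 or any 1 of the 5 vehicle males. For lithium in WT males the count of 14 was 1 without WT lithium male 5 or WT vehicle male 3 or 4, 6 without WT lithium male 4, 8 without WT vehicle male 1 and 26 without WT vehicle male 2. For fluoxetine in WT males the count of 2945 was 1732 without WT vehicle male 2 and 1917 without WT fluoxetine male 1. With the 3 libraries picked by eye left out, the counts were 15 for lithium in HT males, 33 for lithium in WT males and 1075 for the difference between the sexes with lithium in HT.

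Whether the drugs acted differently in HT and WT was tested as an interaction. No gene passed for fluoxetine by limma (1380 at an unadjusted p under 0.05, none by edgeR). Arpp21 (0.30, SE 0.075), Lias (0.23), Ifi27 (-0.54, SE 0.12) and Rlbp1 (-0.50) ranked highest, each with adjusted p = 0.43. No gene passed for lithium by limma (979 at an unadjusted p under 0.05, none by edgeR). The immediate early gene Ier2 had a difference of 1.03 (SE 0.20, adjusted p = 0.094), Tmem108 of 0.44 (SE 0.091, adjusted p = 0.1), Xdh of -0.89 (SE 0.20, adjusted p = 0.22) and Lao1 of -1.94 (SE 0.50, adjusted p = 0.28). For lithium 11 genes passed with 3 libraries left out or without HT lithium male 5 alone, 3 without HT vehicle female 3, and 1 without HT lithium female 2, HT lithium male 3, HT vehicle female 1 or WT lithium male 2. With library weights 234 genes passed for fluoxetine and 40 for lithium.

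Treated HT libraries were also set against vehicle WT libraries, to ask how far they lay from untreated wild type. With fluoxetine 3453 genes were higher and 3447 lower, among them Chd5 (0.40, SE 0.030, adjusted p = 1e-13), Cc2d1a (0.40), Efr3b (0.27) and Nova2 (0.43) upward and Hibadh (-0.41), Zfand6 (-0.50), Laptm4a (-0.38) and Selenof (-0.42) downward. With lithium 2573 genes were higher and 2739 lower, among them Ints1 (0.46, SE 0.043, adjusted p = 2.9e-10), Sgsm1 (0.42), Efr3b (0.21) and Fn1 (0.64) upward and Bche (-0.85), 2810013P06Rik (-0.39), 2500004C02Rik (-0.50) and Fam45a (-0.35) downward. Chd5 (0.112), Cc2d1a (0.217), Nova2 (0.161), Hibadh (-0.236), Zfand6 (-0.326) and Selenof (-0.254) with fluoxetine and Fam45a (-0.167) with lithium were over 1.5 times smaller after the GC and length correction but still passed. Arid1b remained lower than in vehicle WT, at -0.11 with fluoxetine (SE 0.036, adjusted p = 0.0091) and at -0.21 with lithium (SE 0.036, adjusted p = 1.9e-05). With the GC slope as a covariate Arid1b had -0.09 with fluoxetine and no longer passed, while after the GC and length correction it had -0.413 with fluoxetine and -0.461 with lithium, so whether it lay nearer to the WT level with a drug depended on the correction. The GC and length correction lowered the lithium count from 5312 to 2431.

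The effects of the drugs were compared across genes, which are not independent replicates. Fluoxetine and lithium fold changes correlated with r = 0.727 in HT and 0.728 in WT. Each pair shares its vehicle libraries, and unchanged groups sharing them in the same way gave a mean r of 0.51 in both genotypes, with ranges of 0.12 to 0.79 in HT and -0.027 to 0.78 in WT that hold these values (100 simulations). With the vehicle libraries split in 2 parts, r was 0.472 in HT and 0.419 in WT (mean of 20 splits), with covariances of 0.038 and 0.0308 against 0.0499 and 0.0439 unsplit and 0.013 simulated (at most 0.033 in HT and 0.029 in WT). In HT 1550 genes were higher and 1500 lower with both drugs, and in WT 922 and 738, counts that the shared vehicle libraries raise. With each drug set against its own vehicle part, means of 751 higher and 569 lower were shared in HT and 240 and 132 in WT (20 splits, 585 to 945, 349 to 749, 30 to 539 and 6 to 412). Independent lists of those sizes would share 146, 113, 40 and 28. The genotypes share no library for a given drug. Fluoxetine effects in HT and WT correlated with r = 0.629 (simulated mean -0.012, highest 0.55) and lithium effects with 0.455 (-0.037, 0.31). Genes called in both numbered 2100 higher and 2094 lower with fluoxetine (557 and 599 for independent lists) and 703 and 557 with lithium (116 and 97). Unchanged groups and independent lists lack any GC trend or batch common to treated libraries, so higher values need not be drug responses. The pooled values hide the sexes. Female and male effects correlated with 0.662 in HT and 0.656 in WT for fluoxetine (simulated at most 0.62 and 0.48), but with 0.311 and -0.0864 for lithium, within the simulated ranges of -0.46 to 0.51 and -0.5 to 0.49. Within 1 sex the drugs, which share vehicle libraries there, correlated with 0.763 and 0.769 in HT and WT females and 0.491 and 0.442 in males, all within the ranges of unchanged groups (means 0.56, 0.51, 0.49 and 0.55, highest 0.85, 0.84, 0.79 and 0.88).

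The genotype effect shares its HT vehicle libraries with the drug effects in HT. It correlated with them at -0.216 for fluoxetine and -0.238 for lithium, where unchanged groups gave means of -0.49 and -0.51 (-0.77 to -0.0043 and -0.8 to -0.19), and the split gave 0.0289 and 0.0481. The covariance changed sign with the split, from -0.0113 to 0.00201 for fluoxetine and from -0.00924 to 0.00265 for lithium. With the drug effects in WT the genotype effect correlated at 0.37 and 0.478, where unchanged groups gave means of 0.52 and 0.53 (0.19 to 0.76 and 0.049 to 0.8) and the split gave 0.106 and 0.0993.

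**Figure D5:**
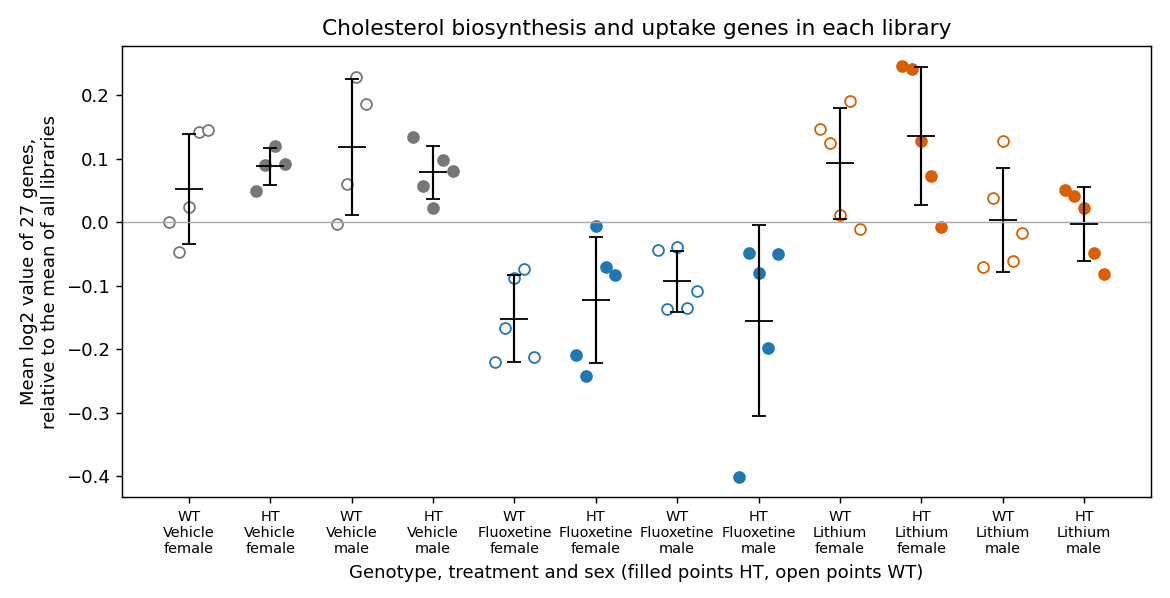
Mean log2 expression of 27 cholesterol genes in each library relative to the mean of all libraries (vertical axis), by treatment and sex (horizontal axis), with open points for WT and filled points for HT. All 20 fluoxetine libraries lie below 0, and lithium females average 0.114.

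Other gene lists passed in none of the 5 main comparisons. Their smallest adjusted p values were 0.069 for 17 oligodendrocyte precursor genes (fluoxetine in WT, median 0.14), 18 upper layer neuron genes (genotype, -0.07) and 21 striatal neuron genes (genotype, -0.16). They were 0.075 for 7 blood genes (fluoxetine in HT, -0.25), 0.084 for 25 endothelial genes (lithium in HT, 0.10), 0.14 for 13 thalamic neuron genes (lithium in WT, 0.17) and 13 mitochondrially encoded genes (lithium in HT, -0.25), and 0.19 for 10 choroid plexus genes (lithium in HT, 0.29). They were 0.29 for 27 GABA receptor and inhibitory synapse genes (genotype, -0.03), 0.32 for 22 neuropeptide genes (fluoxetine in HT, -0.17), and 0.35 for 31 GABAergic interneuron genes (fluoxetine in WT, 0.16), 26 microglial genes (fluoxetine in HT, -0.12) and 20 heat shock genes (lithium in HT, -0.06). They were 0.58 for 15 thyroid hormone response genes (genotype, 0.005) and 0.61 for 5 sex chromosome genes (fluoxetine in WT, -0.25). For heat shock genes with lithium in HT the median and the test pointed down while the mean was 0.0003. The blood list passed after the GC and length correction for fluoxetine in HT (adjusted p = 0.036, against 0.036 to 0.96 over all alternatives), lithium in HT (0.041, against 0.041 to 0.96) and lithium in WT (0.038, against 0.038 to 0.96), and the endothelial list for lithium in HT (0.031, against 0.031 to 0.96).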

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

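The tests of explanations and the counts of other splits were chosen only after the results were seen, except the covariate for myelin genes and the test of X-linked genes. Chance alone marks about 1 in 20 groups as holding a library that stands apart. In 108 tests of 1 measure within 1 group, 9 values stood apart, and they came from 6 libraries.

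A profile of fluoxetine libraries also appeared in lithium females and in 2 lithium males. On a scale where the vehicle groups average near 0 and the fluoxetine groups near 1, lithium females scored 0.788 to 1.06, HT lithium males 4 and 5 scored 0.952 and 1.02, and the other 8 lithium males scored at most 0.15. A gene-level GC and length trend as the whole cause was argued against. In WT, the genotype with fewer, 2614 genes stayed called in the same direction after the correction. GC bias of other forms was not tested. An unrecorded difference between batches of libraries or animals may account for the profile. Of the HT lithium males 2 scored like the females and others like vehicle, with no date or batch recorded. A response to the drugs stays open and cannot be told apart from such a batch, since no record parts the drugs from it and the score, taken along the mean fluoxetine effect itself, shows which libraries are alike but not why. The lowest fluoxetine library scored 0.186 in GC-corrected values, below the highest vehicle library (0.319).

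Cholesterol synthesis and uptake genes were lower in fluoxetine libraries. After the GC and length correction 18 of the 27 genes were lower in WT, the genotype with fewer, arguing against a gene-level GC trend. With the myelin score as covariate 16 were in each genotype, arguing against a smaller oligodendrocyte share. In females the profile shared with lithium females was argued against too, since fluoxetine females scored 0.251 below lithium females (difference -0.251, n = 10 each, 2-sided permutation p = 1e-04, adjusted p = 3e-04 over 3 tests). In males the shared profile and fluoxetine cannot be told apart as the source of the lower scores, because only 2 lithium males hold the profile. These, HT lithium males 4 and 5, scored -0.0492 and -0.0812 on the cholesterol genes, where the other 3 of their group scored 0.0221 to 0.0497, and 2 of the 5 HT fluoxetine males scored below both. WT fluoxetine male 3, which lacks the profile, had the highest score of its group (-0.0392, others -0.137 to -0.0444), while the WT vehicle males scored -0.00284 to 0.228. A response of sterol genes to fluoxetine stays open, beside an unrecorded batch of fluoxetine libraries alone, which was not tested, and the shared profile.

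HT lithium female replicate 4 had 3.74 normalised Xist reads, where the others of its group had 18330 to 22820. A male library with the wrong label was argued against, since its highest Y-linked gene was at 3.74 reads, while the males averaged 1290 for Ddx3y. A single X chromosome may account for it, as 4 of 4 genes that escape X inactivation were lowest in this library among the 29 labelled female (Kdm6a at 646 against a mean of 1020 in the other females, Eif2s3x at 2580 against 4160). Loss of Xist with both X chromosomes expressed was argued against, since the 448 X-linked genes had a median log2 difference of -0.0457 from the other 4 libraries. No biological explanation was tested beyond these.

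HT fluoxetine male 1 had a GC slope of -0.355, where the others of its group had 0.0635 to 0.151. The same library scored 0.417 on the fluoxetine profile (others 0.895 to 1.08), 1.768 on the olfactory markers (others -1.648 to -0.8316) and had 1837 Ddx3y reads (others 1026 to 1239). WT fluoxetine female 2 scored 0.725 on the fluoxetine profile (others 1.04 to 1.09). WT fluoxetine male 3 scored 0.198 (others 0.935 to 1.06). The immediate early gene score of HT lithium female 2 was -0.132 (others 0.173 to 0.272). WT vehicle male 1 scored 1.909 on the olfactory markers (others -1.621 to -1.423). Replicate 1 scored high on these markers in most groups (1.295 to 2.068), so this library and HT fluoxetine male 1 are not isolated cases. By limma the effect of lithium differed between the sexes in 97 genes in HT and 3110 in WT.

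Other splits of the libraries into groups of the same sizes (100, the real one included) test for chance. For a difference between 2 effects, the part alike in both was removed first, since exchanging drug and vehicle in 1 sex or genotype would otherwise add the effects. This removal was added after splits without it were seen. For the genotype 2 gave at least the 8 genes found (highest other 16). Only the real split, 1 of 100, gave as many for fluoxetine in HT (5991, highest other 2755), lithium in HT (3852, 2415) and fluoxetine in WT (6419, 4189), and 2 did for lithium in WT (1835, 3083). Within females 1 did for fluoxetine in HT (3574, 2104) and WT (4412, 1577) and lithium in HT (4064, 2026) and WT (5710, 1260). Within males 1 did for the genotype (4, 2), fluoxetine in HT (3124, 3063) and lithium in WT (14, 9), and 2 for fluoxetine in WT (2945, 3463). The count was 1 for the difference between the sexes with lithium in WT (3110, 58) and for HT with fluoxetine (6900, 5090) or lithium (5312, 2186) against vehicle WT. Chance is excluded at 1 in 20 for each of these 16 comparisons, unadjusted over them. Both genotype counts include the disrupted Arid1b, and the splits did not test the other genes alone.

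Chance is not excluded for the genotype in females (2 genes, 5 of 100 splits, highest other 4) and for lithium in HT males (2 genes, 15 splits, highest other 1855). For the difference between the sexes with lithium in HT it lies at the edge (97 genes, 4 splits, highest other 1141). With nothing removed 5 splits gave as many (highest other 3675), so the removal alone brought it below 1 in 20 and it is not counted among the 16. Where 0 genes were called the splits test nothing, since all 100 must give as many: the difference between the sexes for genotype (highest other 11), for fluoxetine in HT (7) and for fluoxetine in WT (1), and the interaction of genotype with fluoxetine (645) and with lithium (5). Both splits with 1855 and 1141 genes moved HT lithium males 1, 2 and 3 to vehicle and kept 4 and 5. They may reflect another structure of the samples. For lithium in WT the split with 3083 genes exchanged WT lithium male 2 with WT vehicle male 3.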

How the results depend on the processing

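The GC and length correction, the GC slope and olfactory covariates, the 3 libraries left out and edgeR were chosen after the results were seen. The others were planned. No count moved by over 1.5 times with a pseudocount of 5, and the counts for fluoxetine in HT and for fluoxetine-treated HT against vehicle WT moved under no alternative, nor did the counts of 0 for the difference between the sexes in genotype and fluoxetine effects. Of 229 values of named genes, 12 no longer passed with quantile normalisation, 5 without a filter, 0 with a pseudocount of 5, 1 with library weights (9 newly passed), 6 with the replicate block, 20 with only the groups compared (1 newly passed), 29 with the GC and length correction (11 others changed sign, some no longer passing), 14 with the GC slope (1 newly passed), 9 with edgeR (1 newly passed) and 24 without some single library (7 newly passed), while 2 newly passed with the olfactory covariate and 5 with 3 libraries left out. Depth limits genes with a mean under 10 reads, which were not tested. After the GC and length correction 155 of the 229 passed as before in the same direction, 32 of them at under 0.5 times the reported log2 size and 2 at over 1.5 times. Of 454 passing values of members of the described lists, 254 passed in the same direction after that correction, 31 of them at under 0.5 times the size. DESeq2 was not run on recovered reads. The cause was not tested for the changes below, except that fitting only some groups or leaving libraries out uses fewer libraries, and the GC correction removes a trend with GC content by its construction.

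Reported counts are given first and the alternative second. For the genotype 8 became 5 without a filter, 75 with library weights, 17 with only the groups compared, 3 with the GC correction, 14 with the GC slope, 16 with the olfactory covariate and 17 with 3 libraries left out. In females 2 became 1 with quantile normalisation and 0 with only the groups compared. In males 4 became 2 with quantile normalisation, 121 with weights, 1 with only the groups compared, 7 with the olfactory covariate, 8 with 3 libraries left out and 1 by edgeR. With the replicate block the genotype count was 5, in males 2, and for lithium in HT males 1. Quantile normalisation moved the share of called genes that were higher from 50% to 66.7% for genotype, from 75% to 50% for genotype in males and from 100% to 75% for lithium in HT males.

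Library weights, of which HT fluoxetine male 1 had the smallest (0.0671), moved lithium in WT from 1835 to 4149, fluoxetine in HT males from 3124 to 4846, fluoxetine in WT females from 4412 to 6619 and males from 2945 to 5717, lithium in WT males from 14 to 342, the difference between the sexes with lithium from 97 to 2398 in HT and from 3110 to 6581 in WT, and the interactions from 0 to 234 for fluoxetine and from 0 to 40 for lithium. With only the groups compared, lithium in WT moved to 3467, fluoxetine in HT males to 816, lithium in HT males from 2 to 0 and the difference between the sexes with lithium in HT to 33. Quantile normalisation gave 4 for lithium in HT males and 1 for that difference. With 3 libraries left out, lithium in WT had 3219, lithium in HT males 15, lithium in WT males 33, the difference between the sexes with lithium in HT 1075 and the interaction with lithium 11. The olfactory covariate gave 11 for lithium in HT males and 210 for that difference, and edgeR gave 25 for lithium in HT males, 7 for lithium in WT males and 12 for that difference.

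The GC and length correction gave 1483 for lithium in HT (3852), 3622 for fluoxetine in WT (6419), 445 for lithium in WT, 1814 for fluoxetine in HT females (3574), 1089 for lithium in HT females (4064), 4 for lithium in HT males, 1275 and 1361 for fluoxetine in WT females and males, 1397 for lithium in WT females (5710), 6 and 176 for the difference between the sexes with lithium in HT and WT, and 2431 for lithium-treated HT against vehicle WT (5312). The GC slope covariate gave 515 for lithium in WT, 2087 for lithium in HT females, 9 for lithium in HT males, 2101 for fluoxetine in WT females, 850 for lithium in WT females, 34 for lithium in WT males, 4 and 0 for the difference between the sexes with lithium in HT and WT, and 3227 for lithium-treated HT against vehicle WT.

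The GC and length correction turned Arid1b from higher to lower for fluoxetine in HT (-0.0535; females -0.0834, males -0.0236), lithium in HT (-0.101; females -0.166), fluoxetine in WT (-0.111; females -0.143, males -0.0801) and lithium in WT females (-0.182). It also turned Paip2 with lithium in WT females (from -0.279 to 0.0098) and its difference between the sexes (from 0.31 to -0.00574), and the glutamate receptor list with lithium in WT (adjusted p = 0.93, against 0.025 as reported). None of the gene lists passed with an estimated correlation, so the counts of lists fell from 7, 13, 9, 8 and 4 to 0 for genotype, fluoxetine in HT, lithium in HT, fluoxetine in WT and lithium in WT, and quantile normalisation lowered them to 7 for fluoxetine and 5 for lithium in HT. In that order library weights newly called 5, 0, 2, 4 and 3 lists and the GC correction 2, 2, 6, 3 and 3. With the shared vehicle group split, the covariances became 0.00201 and 0.00265 (reversed) for genotype with fluoxetine and lithium in HT, 0.00666 and 0.00428 in WT, and 0.038 and 0.0308 for fluoxetine with lithium in HT and WT.

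Leaving out 1 library at a time gave 1 to 12 genes for genotype (1 to 2 in females, 1 to 4 in males), 5545 to 6838 for fluoxetine in HT (2744 to 3338 in females, 2421 to 3688 in males), 2917 to 4455 for lithium in HT (2925 to 4143 in females, 0 to 27 in males), 5845 to 6833 for fluoxetine in WT (3501 to 4576 in females, 1732 to 3627 in males) and 1046 to 1853 for lithium in WT (4698 to 5477 in females, 1 to 26 in males). The difference between the sexes ranged from 0 to 0 for genotype and for fluoxetine in HT and in WT, from 6 to 418 for lithium in HT and from 1788 (without WT vehicle male 3) to 3608 for lithium in WT. For lithium in HT it was 6 without HT lithium male 3, 18, 26, 375 and 418 without HT lithium male 1, 2, 4 and 5, 28 and 35 without HT lithium female 2 and 3, 25 without HT vehicle female 1 or 3, and 28 and 47 without HT vehicle male 2 and 4. The interaction ranged from 0 to 0 for fluoxetine and from 0 to 11 for lithium, and treated HT against vehicle WT from 6336 to 7747 for fluoxetine and from 4344 to 5872 for lithium.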

Other observations

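The comparisons of fluoxetine with lithium were chosen only after the results were seen.

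Fluoxetine and lithium females differed in cholesterol genes and in blood transcripts (10 libraries each, both genotypes). Of 27 cholesterol genes, 19 were lower with fluoxetine than with lithium and none higher (23 lower adjusted over the list alone), with a median log2 difference of -0.26 (adjusted p = 2.1e-27; adjusted p = 0.02 with an estimated correlation). Acat2 was lower by -0.34 (SE 0.044, adjusted p = 7.6e-06), Fdps, an enzyme of isoprenoid synthesis, by -0.38 (SE 0.054) and Insig1 by -0.34 (SE 0.058). In males 13 of the 27 were lower, with a median of -0.15 (adjusted p = 8.5e-05, and 0.75 with an estimated correlation).

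Of 7 blood genes, 5 were lower with fluoxetine than with lithium in females (7 adjusted over the list alone), with a median of -1.01 (adjusted p = 4.5e-11; adjusted p = 0.068 with an estimated correlation). In males 4 were lower (6 adjusted over the list alone), with a median of -0.53 (adjusted p = 0.003; adjusted p = 0.75 with an estimated correlation). In females Alas2, the first enzyme of heme synthesis in red cells, was at -1.04 and the globin gene Hbb-bs at -1.01. Globin genes share reads with their close paralogs, so single members are uncertain. Against vehicle, the blood list in HT had a median of -0.25 with fluoxetine (3 of 7 lower) and 0.46 with lithium (3 higher and 1 lower), and neither passed as a list (adjusted p = 0.075 and 0.1). In all, 187 genes were higher and 244 lower with fluoxetine than with lithium in females, and 2111 higher and 2126 lower in males. After the GC and length correction 675 genes were called in females, 375 of them called before in the same direction, and 2693 in males, 2023 of them called before.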
